A study of Mus musculus with 6 samples.

How the data were processed

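Total RNA from 6 samples of cultured astrocytes, 3 infected with a control lentivirus and 3 with a Cre lentivirus, was amplified to aminoallyl RNA, coupled to Cy5 and hybridised to 1-colour oligonucleotide arrays, per the labels' protocols. The deposited scanner files hold 1 median intensity per spot and 1 local background intensity, not subtracted from each other, per the file headers. Each array carries 23474 probe spots for 23473 probes, 2736 blank spots and 1246 other control spots. The authors also deposited a table of processed values on a linear intensity scale. Set against the scanner files, each of its columns was the spot median less about the mean of the blank spots, divided by 1 factor per array (1.44 to 1.94), so that every column's median was 25, with empty cells near the blanks (1609 to 3178 per array). How those factors were chosen is not given in the sources used here, and neither is any other processing step. All columns of per-sample values matched a sample. No genome build is named, so no coordinates are given.

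Probe names came from the platform annotation supplied with the series, updated through Entrez identifiers against RefSeq's table for GRCm38.p6. Of the 23473 probes, 20690 had 1 gene symbol, 0 had several and 2783 were unnamed here; 20556 matched the table and 0 symbols changed.

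Blank spots averaged 62.4 to 70.8 intensity units and the median probe spot 88.8 to 106. A probe counted as above background where its spot exceeded the mean of the blank spots by 2 SD; this held for 82.9 to 87.0% of probes on Cre arrays and 87.4 to 90.8% on control arrays. The authors' table had more empty cells for each Cre array (2271 to 3178) than for any control array (1609 to 2176). The local background column was not used for the main setting, because it followed the signal of the spot itself: it averaged 179 to 322 units around probe spots and 57.5 to 63.0 around blank spots, and in Cre replicate 2 it reached 95.3% of the spot's own value among the brightest 10% of spots. Intensities were therefore corrected by normexp against the blank spots (limma's nec, offset 50), although the design had put the local background first; this was settled before any test was run. They were then log2 transformed and quantile normalised between arrays. The offset and the correction compress fold changes of dim probes. Spots marked by the scanner were left out (0 to 9 per array), and spots of 1 probe were averaged. Probes above background on at least 3 of the 6 arrays were kept, 20542 in number.

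Cre and control cultures were compared with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 20542 probes and a threshold of 0.05; the Chd7 result was judged over its 2 probes. Gene lists were compared with limma's camera at its preset correlation of 0.01, on the brightest probe of each of 17120 genes, for 32 lists that together hold 750 entries, 681 of them measured; estimated correlations and fry served as alternatives. List members were also adjusted over the list alone, a measure that does not correct for the number of lists. Camera sets a list against all other genes, while fry asks only whether the list's own genes move. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1. The labels do not say whether the 3 replicates of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

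Replicate numbers are shared by both groups in the labels. Deviations from the group means correlated at 0.498, 0.425 and 0.436 between same-numbered arrays, so the numbers were taken to pair the samples. Other arrays correlated at -0.373 to -0.167. Deviations sum to 0 within a group, so these negative values follow from the positive ones and add no evidence. The pairing comes from the numbers and this correlation; the labels do not state a shared litter, culture or day. The design without a block had been fixed as the main one, and a fit with the replicate number as a block was run beside it.

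Named genes followed a rule fixed before the data were examined, as were the design, the gene lists and most of the alternatives. Chd7 came first, with both probes. Genes past the threshold came next, and since there were none, the 6 with the smallest unadjusted p in each direction, as values that did not pass. Each list that passed gave up to 4 members with the smallest p in its direction and each other list up to 2. The brightest probe stood for a gene; 2 named genes had another kept probe, of which 1 had the other sign (Gli2). Genes named outside the rule are marked as chosen after their values were seen.

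The fit was tested on simulated data for Cre against control, with 200 of 20521 probes changed in each of 20 runs. Each probe's spread was drawn from the distribution of variances that limma fitted to these arrays, whatever its brightness, with normal noise. Recovery was 66.9% for 1.5-fold, 85.9% for 2-fold and 95.1% for 4-fold changes, and 4.84% of the calls were false. These rates hold for that many changed probes, for arrays without pairing and for data that follow limma's own model. With 5 of 32 lists of 20 genes shifted by 0.2 log2 units, 100% were recovered and 0% of the others were called; the simulated genes were independent, while the correlation estimated within the lists reached 0.78, and other splits of the real arrays gave up to 13 list calls. Alternatives covered the background correction, the scaling, the authors' values, the filter on dim probes, the replicate block, the variance model, the set test, the probes of a gene and each array left out in turn. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9 were used.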

Results

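Gene expression was measured in cultured astrocytes of newborn mouse cortex that carried floxed Chd7 alleles, in which the Cre recombinase removes the flanked part of the gene. Chd7 encodes an ATP-dependent chromatin remodeller of the chromodomain helicase family. The cells received a control lentivirus on 3 arrays or a lentivirus carrying Cre on 3 arrays, and RNA was taken 3 days after infection from cultures kept in 10% serum with FGF2, EGF and B-27. Each sample was hybridised to its own 1-colour array of 23473 probes. Between 19452 probes (82.9%, Cre replicate 2) and 21305 probes (90.8%, control replicate 2) lay above background on an array. All 3 Cre arrays (82.9, 83.4 and 87.0%) had fewer probes above background than the 3 control arrays (87.4, 87.7 and 90.8%). The number of arrays limits the precision. Log2 intensities of any pair of arrays correlated across probes with r of 0.985 to 0.995.

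The first comparison was of Chd7 itself, the gene the Cre virus was to inactivate. The brighter Chd7 probe, M300016343, fell from 7.12 ± 0.32 (SD, n = 3) to 5.99 ± 0.02 log2 units, a difference of -1.13 (SE 0.16, 95% interval -1.53 to -0.74), or 2.2-fold. It was lower in the Cre array of every same-numbered pair, by -0.93, -1.53 and -0.95. In the authors' linear values the same probe read 59 ± 26.1 in control and 7.67 ± 0.58 in Cre cultures (SD, n = 3), so that 13% of the control value was left. The limma adjusted p was 0.00103 over the 2 Chd7 probes and 0.406 over all probes tested, and an exact two-sided permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow. The other Chd7 probe, M400002483, lay close to background at 6.14 ± 0.06 in control and 6.03 ± 0.08 in Cre cultures (SD, n = 3), a difference of -0.11 (SE 0.06) that did not pass (limma adjusted p = 0.122 over the 2 probes). In the authors' values M400002483 read 12.67 ± 1.53 in control and 8.67 ± 2.52 in Cre cultures (SD, n = 3), or 68.4% of the control value. The 2 probes thus differ in the share of Chd7 signal left. Where the probes lie relative to the floxed part of Chd7 is not given in the sources used here.

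Across the transcriptome, the question was which transcripts differ between astrocytes given the control virus and the Cre virus. Besides Chd7, a difference of more than 2-fold with no overlap between the groups was measured for Gdnf, the gene of a neurotrophic factor, at 11.38 in control and 10.33 in Cre cultures, a log2 difference of -1.05 (SE 0.10, n = 3 per group). Next to it among the smallest p-values for lower levels stood Serinc5, a membrane protein that incorporates serine into lipids, at -0.49 (SE 0.04), Cyb5r1, a cytochrome b5 reductase, at -0.60 (SE 0.06), the linker histone H1f2 at -0.56 (SE 0.07), Cyp2c39 at -0.51 (SE 0.07) and the transcription cofactor Dach2 at -0.61 (SE 0.08). The smallest p-values for higher levels belonged to the collagen chain Col9a3 at 0.41 (SE 0.03), the tetraspanin Cd81 at 0.49 (SE 0.05), Plek2 at 0.53 (SE 0.06), the secreted ligand Wnt4 at 0.32 (SE 0.04), the mitochondrial carrier Slc25a30 at 0.59 (SE 0.07) and the leukotriene receptor Ltb4r1 at 0.37 (SE 0.05). Of the genes with higher levels, Wnt4, Ltb4r1 and Plek2 lay close to background in control cultures, at 6.03, 6.11 and 6.22 log2 units. In all 12 genes the 3 Cre arrays did not overlap the 3 control arrays, which picking by the smallest p-values favours. None passed (limma adjusted p = 0.406 for each).

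In the count over all probes, 0 of 20542 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.406. At an unadjusted p under 0.05 there were 1154 probes, 568 higher and 586 lower in Cre cultures. By chance 1027.1 would be reached in unpaired arrays. With the replicate number as a block there were 1918, for the same expectation of 1027.1, and again 0 past the adjusted threshold. Other splits of the arrays were not run with the block, so how far such a count varies without a group difference is not known. The groups did not overlap for 2167 probes (10.5%), against 10% by chance in unpaired arrays. The pairing of the replicates lowers both chance values given for unpaired arrays. A difference of at least 2-fold was measured for 5 probes, all lower in Cre cultures. These were the Gdnf and Chd7 probes, the casein gene Csn3 at -1.02 (SE 0.20), a probe of Mrpl47 at -1.25 (SE 0.96) and Tubb5 at -1.14 (SE 1.20); the last 3 are named after their values were seen. Arrays were also simulated with spreads drawn from limma's fit, 200 changed probes per run and no pairing. At this threshold, 85.9% of 2-fold and 66.9% of 1.5-fold changes were recovered. These rates do not carry over to fewer changes, where the adjusted threshold is harder to pass. Here Chd7 and Gdnf, both over 2-fold, stood at a limma adjusted p of 0.406.

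**Figure D1:**
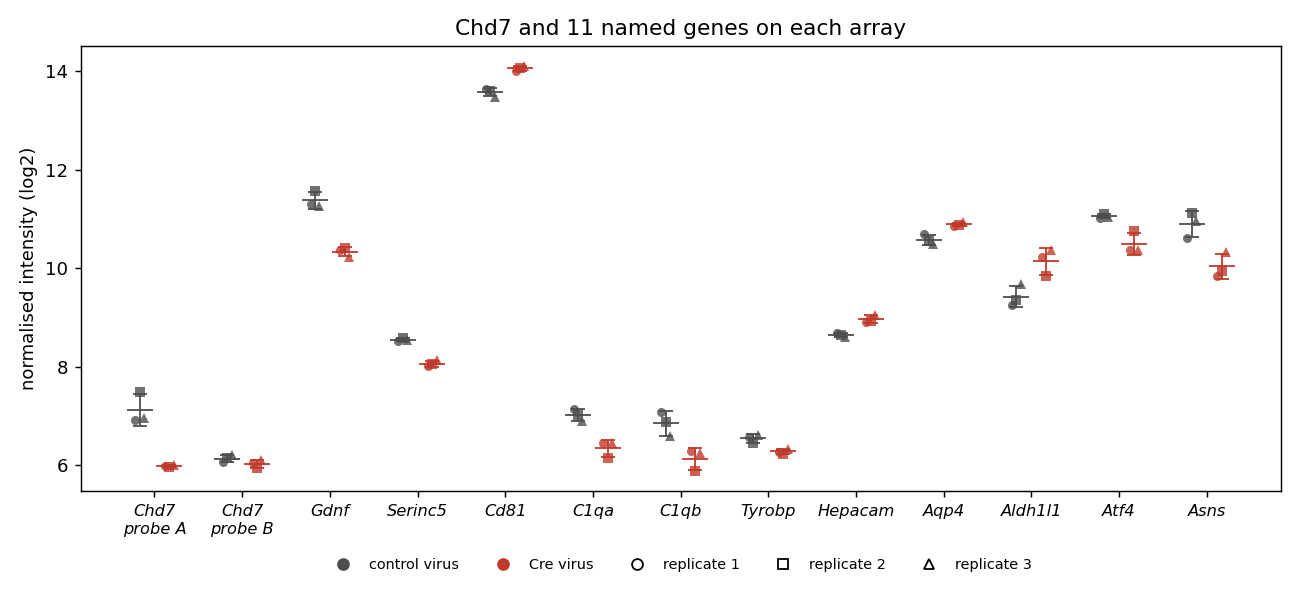
Log2 normalised intensity (vertical axis) of both Chd7 probes (A is M300016343, B is M400002483) and of 11 named genes on each control virus array (grey) and Cre virus array (red), with replicate numbers as symbols and bars for the mean and SD of 3 arrays. Chd7 probe A stands at 7.12 in control and 5.99 in Cre cultures and Gdnf at 11.38 and 10.33, with no overlap between the groups.

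Markers of microglia and macrophages, immune cells that astrocyte cultures can hold, fell as a group: 16 of the 20 measured genes were lower in Cre cultures, with a median log2 difference of -0.17 (camera adjusted p = 4.43e-05; adjusted p = 0.475 with an estimated correlation). Adjusted over the list alone, 8 members passed, and 0 did over all probes. The complement genes C1qa at -0.67 (SE 0.11), C1qb at -0.71 (SE 0.17) and C1qc at -0.37 (SE 0.10), whose products form the first complement component, fell by that measure, as did the signalling adaptor Tyrobp at -0.26 (SE 0.06). Cd68, which encodes a lysosomal glycoprotein and is named after its value was seen, rose (0.48, SE 0.08), the only one of the 8 to do so. The median was below 0 in all 3 same-numbered pairs, at -0.22, -0.19 and -0.11. Its size depended on the background. Relative to the median of all probes it was -0.59 with plain subtraction of the blank mean, -0.51 in the authors' values and -0.03 with the local background column, where the call was lost.

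Astrocyte markers rose as a group in the same cultures in which microglia markers fell, with 20 of 24 measured genes higher and a median of 0.20 (camera adjusted p = 0.000967; adjusted p = 0.763 with an estimated correlation). Adjusted over the list alone, 2 members passed: the adhesion molecule Hepacam at 0.32 (SE 0.05) and the water channel Aqp4 at 0.31 (SE 0.06). Aldh1l1, an enzyme of folate metabolism, stood at 0.72 (SE 0.17) and the glutamine synthetase gene Glul at 0.23 (SE 0.08), and neither passed. The median of the list was 0.20, 0.03 and 0.28 in the 3 pairs. Without control replicate 1 the call was lost (median 0.02, adjusted p = 0.0824).

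**Figure D2:**
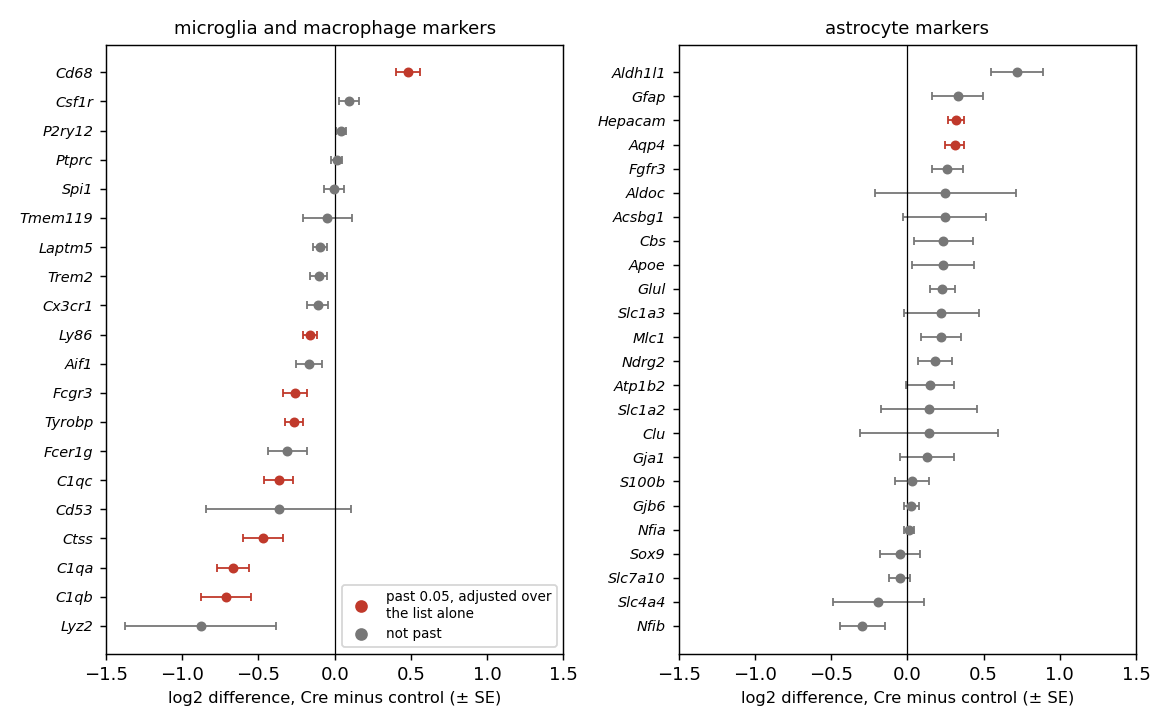
Log2 difference of Cre minus control (horizontal axis) for each measured marker of microglia and macrophages (left) and of astrocytes (right), with bars for the standard error from limma; red points passed 0.05 when adjusted over the list alone. In the left panel 16 of 20 genes lie below 0 and in the right panel 20 of 24 lie above it.

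Target genes of the stress regulator p53 rose as a group, with 21 of 28 measured genes higher and a median of 0.08 (camera adjusted p = 0.00108; adjusted p = 0.415 with an estimated correlation). The 4 members with the smallest p in that direction were the epoxide hydrolase gene Ephx1 at 0.31 (SE 0.08), the spindle protein gene Ckap2 at 0.39 (SE 0.10), the carbonyl reductase gene Dcxr at 0.21 (SE 0.06) and the kinase gene Plk3 at 0.14 (SE 0.05). None of the 28 passed, either over all probes or adjusted over the list alone. Ephx1 and Dcxr encode metabolic enzymes; Cdkn1a, a cell cycle inhibitor named after its value was seen, stood at 0.29 (SE 0.16). The median of the list was 0.11, 0.16 and 0.12 in the 3 pairs.

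Glycolysis genes also rose as a group, with 17 of 21 higher and a median of 0.10 (camera adjusted p = 0.00144; adjusted p = 0.415 with an estimated correlation). Gapdh stood at 0.22 (SE 0.06), the pyruvate kinase gene Pkm at 0.33 (SE 0.11), Pfkl at 0.20 (SE 0.08) and the glucose transporter gene Slc2a1 at 0.28 (SE 0.14), and 0 members passed adjusted over the list alone. The median was 0.06, -0.002 and 0.20 in the 3 pairs. Without Cre replicate 3 the call was lost (median 0.07, adjusted p = 0.0552). Genes of cytosolic ribosomal proteins fell as a group, with 26 of 34 lower and a median of -0.06 (camera adjusted p = 0.00368; adjusted p = 0.763 with an estimated correlation). Rps6 stood at -0.19 (SE 0.08), Rpl4 at -0.15 (SE 0.07), Rps24 at -0.13 (SE 0.07) and Rps4x at -0.18 (SE 0.10), and 0 members passed adjusted over the list alone. The median was 0.0005, -0.007 and -0.13 in the 3 pairs. The call was lost without control replicate 3 (median -0.02, adjusted p = 0.511) and with plain subtraction of the blank mean (median -0.07, adjusted p = 0.124).

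The remaining 27 of the 32 lists did not pass, with adjusted p between 0.125 and 0.918 and medians between -0.08 and 0.08. Of their measured members, 20 were higher and 14 lower at an unadjusted p under 0.05, and 0 passed over all probes. Of these lists, 10 passed in some fit with 1 array left out. In 7 lists the median, the mean and the test differed in sign: neural stem cells, oligodendrocytes, fibroblasts, S phase, TGF-beta and SRF/YAP targets, BMP targets and the Notch pathway.

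Among markers of other cells, the neuroblast and neuron list (22 genes, adjusted p = 0.350) had 2 members past the threshold adjusted over the list alone. These were the transcription factor gene Neurod1 at 0.46 (SE 0.07) and the neurofilament gene Nefm at 0.39 (SE 0.07). Both are dim probes: Neurod1 lay close to background at 5.87 log2 units in control and 6.32 in Cre cultures, and Nefm at 6.31 and 6.70. In the neural stem and progenitor list (19 genes, adjusted p = 0.840), 1 member passed that way, Prom1, the gene of the surface protein prominin, at 0.61 (SE 0.08), while Id3 stood at 0.18 (SE 0.06). The oligodendrocyte lineage list (adjusted p = 0.918) was led by Cldn11 at 0.14 and Gal3st1 at 0.14. The fibroblast and mural cell list (adjusted p = 0.840) was led by Col5a1 at 0.51 and Des at 0.05, the endothelial list (adjusted p = 0.610) by Ly6c1 at 0.14 and Sox18 at 0.07, and the ependymal list (adjusted p = 0.840) by Tmem212 at 0.05 and Cfap126 at 0.24.

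Genes of the unfolded protein and amino acid stress response went both ways (25 genes, median near 0, mean -0.15, adjusted p = 0.343). Atf4, the transcription factor that turns on amino acid supply genes, fell when adjusted over the list alone (-0.56, SE 0.12), and so did the asparagine synthetase gene Asns (-0.86, SE 0.18). The third member past that threshold was the protein folding enzyme Pdia4, named after its value was seen, at 0.32 (SE 0.07). In cholesterol synthesis (18 genes, adjusted p = 0.125), the squalene synthase gene Fdft1 fell by that measure (-0.52, SE 0.08) while 13 of the 18 genes lay above 0, among them Sc5d at 0.27 (SE 0.07). By fry's test for changes in either direction, cholesterol synthesis and the neuroblast and neuron list passed (adjusted p = 0.0064 for both). Respiratory chain genes (adjusted p = 0.125) were led by Ndufv1 at 0.23 (SE 0.07) and Cox7a2 at 0.16 (SE 0.07).

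Reactive astrocyte genes did not pass as the pan-reactive set (adjusted p = 0.132), the neuroinflammation set (adjusted p = 0.501) or the ischaemia set (adjusted p = 0.682). Their leading members were S1pr3 at 0.37 (SE 0.09) and Gfap at 0.33 (SE 0.17), Fbln5 at -0.54 (SE 0.13) and Iigp1 at -0.60 (SE 0.32), and Cd109 at 0.34 (SE 0.09) and Clcf1 at -0.17 (SE 0.08). The interferon response (adjusted p = 0.184) was led by Rtp4 at -0.41 and Tap1 at 0.16, antigen presentation (adjusted p = 0.274) by Tap1 and H2-Ab1 at 0.10, and inflammatory cytokine genes (adjusted p = 0.558) by Icam1 at 0.34 and Il1b at -0.10. Proliferation genes stood at an adjusted p of 0.918 for S phase, with Rfc3 at -0.12 and Rrm2 at 0.43, and 0.558 for G2 and mitosis, with Cks2 at -0.23 and Kif23 at 0.14.

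Genes linked to CHD7 in other cell types did not separate the groups, with 6 of 18 higher, 12 lower and an adjusted p of 0.866; Sox11 stood at 0.08 (SE 0.05) and Gli2 at 0.21 (SE 0.17), while a dimmer Gli2 probe read -0.03 (SE 0.04). The remodeller genes of the CHD and SWI/SNF families (adjusted p = 0.553) were led by Smarca5 at -0.23 and Ep400 at 0.05. Signalling lists were at an adjusted p of 0.132 for Wnt (Fzd1 at 0.14, Dkk1 at -0.08), 0.184 for Hedgehog (Gas1 at 0.16 and Gli2), 0.840 for BMP targets (Id3 and Id1 at -0.09), 0.866 for Notch (Hey2 at -0.14, Jag2 at -0.12), 0.918 for FGF and EGF feedback (Spry2 at 0.29, Dusp4 at 0.16) and 0.918 for TGF-beta and SRF/YAP targets (Tgfb1i1 at -0.44, Axl at 0.45). With the replicate number as a block, the Wnt list passed (adjusted p = 0.0296), and this call was lost too (adjusted p = 0.732 with the block and an estimated correlation). Axon guidance genes (adjusted p = 0.866) were led by the ephrin receptor genes Epha5 at -0.60 (SE 0.16), whose other probe read -0.56 (SE 0.08), and Epha7 at -0.14 (SE 0.04). Synapse-regulating factors of astrocytes (adjusted p = 0.558) were led by Tgfb2 at 0.28 (SE 0.09) and Nlgn1 at -0.16 (SE 0.07).

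**Figure D3:**
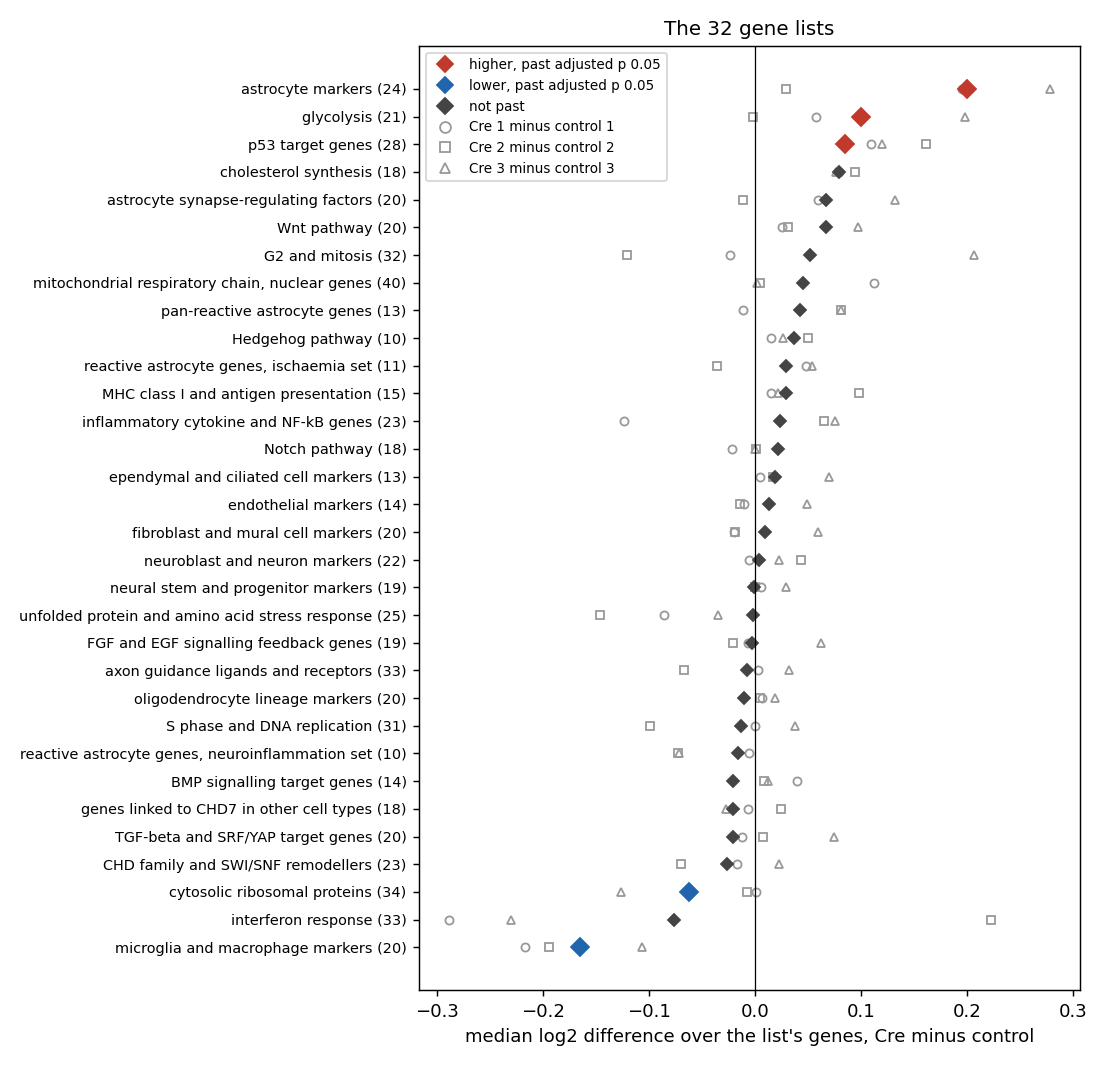
Median log2 difference of Cre minus control over the measured genes of each of the 32 lists (filled diamonds; number of genes in parentheses), coloured where the camera adjusted p was under 0.05, with the median of each same-numbered pair of arrays as open symbols. Microglia and macrophage markers lie at -0.17 and astrocyte markers at 0.20, and the pairs of the interferon list lie on both sides of 0.

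No list passed with an estimated correlation between genes (smallest adjusted p = 0.415), and with the scanner's local background in place of the blank spots the calls of the microglia, astrocyte, p53 and glycolysis lists were lost (adjusted p between 0.334 and 0.906), the medians relative to all probes were -0.03 for microglia, 0.17 for astrocytes, 0.004 for p53 and -0.09 for glycolysis, the ribosomal protein list kept its call at -0.61 (adjusted p = 0.00484), and 23 named genes changed sign, of which Tyrobp (0.020) lay below the median of all probes (0.03). Cre itself was present only in the cultures where Chd7 was targeted, so that effects of the recombinase and of Chd7 loss cannot be told apart here.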

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

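The local background column, and the replicate block together with an estimated correlation, were chosen after seeing the data. Chd7 kept its direction and stayed past 0.05 over its 2 probes under every alternative run, between -2.86 (the authors' values) and -0.52 (local background column), and between -1.25 and -0.92 with 1 array left out. The count of probes past the adjusted threshold was 0 under every alternative, the replicate block (0) and a 2-fold limit included, with a smallest adjusted p of 0.0719 without control replicate 2; at an unadjusted p under 0.05 the count ranged from 613 (median scaling) to 2075 (the authors' values), whose median over all probes was shifted by -0.17. The 5 list calls became 9 with median scaling, 1 with the local background column (ribosomal proteins, median -0.58, adjusted p = 0.00484), and 0 with an estimated correlation, with fry and with the replicate block plus an estimated correlation; they were 6 with the replicate block alone, which added Wnt (adjusted p = 0.0296) and changed no other call. With 1 array left out they numbered between 5 and 9. The microglia and p53 lists passed each time. The astrocyte list was lost without control replicate 1 (camera adjusted p = 0.0824) and glycolysis without Cre replicate 3 (0.0552). Ribosomal proteins were lost without control replicate 3 (0.511) and with plain subtraction (0.124), the latter at a median of -0.07 against -0.06 in the main setting. Relative to all probes, the 5 lists kept their signs with both scalings below. Median scaling added the pan-reactive, Wnt, interferon and amino acid stress lists, and the authors' values (7 calls) the first 2. With 1 array left out, G2 and mitosis passed as higher (camera adjusted p = 0.000873 without control replicate 2 and 3.65e-05 without Cre replicate 1). Interferon passed as lower (1.55e-07 without control replicate 2 and 0.0325 without Cre replicate 3). The respiratory chain passed as higher (0.00106 without control replicate 2, 0.0269 without control replicate 3 and 0.00436 without Cre replicate 1). Cholesterol synthesis, the pan-reactive set, Wnt, cytokine genes, S phase and antigen presentation passed in 1 or 2 such fits (0.0114 to 0.0444). TGF-beta and SRF/YAP targets passed as lower without Cre replicate 1 (-0.22, adjusted p = 0.0311); with 1 array left out their range was -0.22 to 0.23. Of 1243 values of 83 named genes, 1217 kept their sign and 26 reversed, none of them past the threshold on either side. With the authors' values these were Id3 (-0.012), Cox7a2 (-0.039) and Gas1 (-0.017), all above the shift of that setting. With the local background column they were Cyb5r1 0.069, Aldh1l1 -0.25, Glul -1.42, Tyrobp 0.020 (below that setting's shift of 0.03), Col5a1 -0.33, Ephx1 -2.56, Rtp4 0.20, Tap1 -0.17, Iigp1 0.16, Clcf1 0.28, Fdft1 0.19, Sc5d -0.43, Gapdh -0.55, Pkm -0.73, Rpl4 0.70, Rps24 0.034, Cox7a2 -0.27, Dusp4 -0.13, Jag2 0.17, Fzd1 -0.029, Dkk1 0.20, Epha5 0.21 and Tgfb2 -0.19. The causes were not tested, except that the local background column rises with the spot's own signal. Of 488 directions of lists not past in either setting, 49 were opposite. A slide or scan block was not run, since no file gives a batch of over 1 array. Probes near the blank spots limit the microglia list: plain subtraction gave its median as -0.59 and the main setting as -0.17.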

Other observations

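The tests on the second lists of genes below were set out before their results were seen, after the patterns themselves had been noticed. Same-numbered control and Cre samples shared large differences in contractile genes and, in part, in proliferative ones. As the median deviation of a list's genes from their mean over 6 arrays, TGF-beta and SRF/YAP targets stood at 0.39 in control replicate 1 and 0.47 in Cre replicate 1, at -0.38 and -0.32 in both replicates numbered 2, and at -0.11 and -0.02 in those numbered 3. G2 and mitosis genes stood at -0.25 and -0.24 in both replicates numbered 1 and at 0.23 and 0.13 in those numbered 2, while those numbered 3 differed, at -0.002 in control and 0.23 in Cre. Interferon response genes ranged from -0.27 (control replicate 2) to 0.38 (control replicate 3), and the Cre minus control difference of that list was -0.29, 0.22 and -0.23 in the 3 pairs. These spans between replicates are wider than the differences of -0.02, 0.05 and -0.08 between the groups in the same lists.

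In amino acid supply, several genes under control of Atf4 had values below 0 in all 3 pairs, though none of these passed adjusted over the list alone: Trib3 at -0.53 (SE 0.13), Chac1 at -0.67 (SE 0.21) and the cystine transporter gene Slc7a11 at -0.38 (SE 0.12), named after their values were seen. Other genes of the same list were less uniform, also named after their values were seen: Psat1 stood at -0.12 (SE 0.26), Phgdh at 0.04 (SE 0.13) and Sesn2 at 0.08 (SE 0.06), and Slc7a5 at -0.35 (SE 0.26) with pair 3 at 0.001. The chaperone gene Hspa5, also named after its value was seen, stood at 0.06 (SE 0.11), and Pdia4 rose. In the second list below, the enzyme genes Pck2 at -0.57 (SE 0.16), Cth at -0.61 (SE 0.18) and Psph at -0.52 (SE 0.22) had values below 0 and Ddit4 at 0.52 (SE 0.14) above it; they too were picked after their values were seen, and none passed adjusted over that list alone (adjusted p of 0.113 or more). In cholesterol synthesis, Hmgcs1, named after its value was seen, stood at 0.70 (SE 0.20), opposite to Fdft1.

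The splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. All 10 gave 0 probes past the adjusted threshold, so the highest other count was 0. At an unadjusted p under 0.05 the real split gave 1154 probes and the highest other 1456, and 6 of the 10 splits, the real one included, gave at least 1154. Because the numbers pair the samples, the real split is best set beside the 3 others that part all pairs, of which the highest gave 716. With 4 such splits in all, being the highest decides nothing. The splits that keep a pair together gave 1121 to 1456, which points to the structure of the replicates. The groups did not overlap for 2167 probes in the real split, against 1659 at most in the 3 others that part all pairs and 2045 to 2798 in those that keep a pair together. For gene lists, 7 of the 10 splits gave at least the real count of 5, the highest other being 13, and 7 among the splits that part all pairs.

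One hypothesis for the lower microglia and macrophage markers is a smaller share of those cells in the Cre cultures. Another is a drift shared by dim probes in general. Medians of 10000 random lists matched on signal had a central 95% from -0.03 to 0.03. Quantile normalisation gives all arrays the same distribution and so holds such medians near 0, whatever drift came before it. These random lists therefore cannot decide on that drift. The list's median of -0.17 lay at the 0.01 percentile, the lowest possible. The list had been noticed for its low values, so that rank adds little of its own. Random lists also leave out the spread between arrays. Without regard to sign, the list's median was 0.165 in the real split of the 6 arrays and 0.005 to 0.139 in the others. The highest of the others that part all pairs was 0.106. With 10 splits, being the highest decides nothing. Background effects on these probes alone are not covered by the matching. All 3 Cre arrays had fewer probes above background (82.9 to 87.0%) than the control arrays (87.4 to 90.8%). A second list of 39 measured microglia and macrophage genes, none of them in the first, had 28 lower and a median of -0.03 (0.02 percentile). Its pair medians were -0.07, -0.03 and -0.004, the last of them close to 0. This met the test and is what fewer such cells would give, but the fall lay in dim probes. The lower members, among them Ms4a7 at -0.64 (SE 0.16), stood at 6.74 log2 units or less in control cultures. The brightest members lay above 0. Cyba stood at 0.20 (SE 0.46), Ctsh at 0.23 (SE 0.45), the lysosomal protease gene Lgmn at 0.22 (SE 0.04) and Rgs10 at 0.06 (SE 0.12). All genes named from this list were picked after their values were seen, and none passed the threshold over the list alone. With an estimated correlation the list gave camera p = 0.193, against 0.00463 with the preset one. Random lists do not carry the correlation between genes of 1 cell type. Above the blank spots, the 9 brightest genes of the first list held in Cre cultures 49.5% (Lyz2), 146% (Cd68), 40.1% (C1qa), 67.2% (Fcer1g), 56.0% (Cd53), 80.5% (Aif1), 31.5% (C1qb), 57.3% (C1qc) and 113% (Csf1r) of the control signal, so that 7 were lower and 2 higher. Over all 20 genes 16 were lower and 4 higher, the dimmest of them too near the blank spots to weigh. Named after their values were seen, Spi1 held 98.4%, and the dim genes P2ry12 and Ptprc 114% and 102%. A smaller share of cells alone does not account for Cd68, and Csf1r and Spi1 did not clearly fall either. Lower expression per cell, after loss of Chd7 or exposure to Cre, was not tested and stays open, and so does the choice of background, since with the local background column the median of the first list relative to all probes was -0.03 and its call was lost.

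A second hypothesis is that ATF4 target genes were lower as a group in the Cre cultures. A second list of 30 measured targets, none of them in the fixed list, had 22 lower and a median of -0.09, at the 0.06 percentile of 10000 matched random lists. Its median was -0.16, -0.15 and 0.03 in the 3 pairs, and the test had asked for all 3 below 0, so the third pair keeps it undecided. With an estimated correlation the list gave camera p = 0.164, against 0.00169 with the preset one. Whether Chd7 loss, Cre or the medium of single samples was behind it was not tested.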
